A study of Mus musculus with 58 samples.

How the data were processed

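RNA from the midbrain of 12-week-old C57BL/6 mice, an inbred laboratory strain, was sequenced in 24 samples, 6 in each of 4 groups given by sex and by treatment, either developmental exposure to dieldrin or control. Dieldrin is an organochlorine insecticide of the cyclodiene type. Per the labels' protocols, it was given at 0.3 mg/kg every 3 days in corn oil on peanut butter pellets, and for the developmental exposure the mothers were dosed. The labels also describe 34 samples of reduced representation bisulfite sequencing, 24 from the developmental and 10 from an adult exposure, and these were not analysed here.

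For each RNA sample, 2 tables of transcript quantities were used. The deposited quantification tables gave for each transcript an estimated count of reads that need not be whole, per the file headers. The same deposited tables gave TPM, a transcript's length-scaled share of the library, which the authors' quantification scaled by effective length and which was not tested here. Transcript length and effective length in bases were other columns of the deposited tables, per the file headers. The second deposited table of each sample held estimated counts that were identical to those of the first in all 24 samples, so using it in place of the first could change no value. The submitters' processing notes name Trim Galore, Bismark 0.19.1, Bowtie2 2.3.2, sleuth and the mouse genome build mm10, without saying which was used for which assay. The program and annotation behind the RNA quantities are not given in the sources used here.

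Each table listed the same 112092 transcripts by Ensembl transcript identifier. The tables do not pair these identifiers with genes or gene names, and 0 of the 112092 matched the reference tables of gene names used here. The tests were therefore run per transcript, as had been foreseen before the data were examined. The 32 gene lists fixed before the data were examined (dopaminergic neurons, GABA receptors, glia, inflammation and others) could not be tested, and no gene is named. Reads compatible with several transcripts of a gene, or with similar genes, were divided among them by the authors' quantification. A change of a transcript can thus come from a shift of reads between transcripts that overlap.

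Estimated counts were rounded to whole numbers. Transcripts were kept by edgeR's filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 61692. Counts were scaled by TMM factors, a mean was fitted for each of the 4 groups over all 24 libraries, and contrasts were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The 5 contrasts were dieldrin against control in males, in females, the difference of these effects (females minus males), their mean, and females against males averaged over treatments. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of the F statistic, with 95% confidence intervals from the moderated degrees of freedom. Values in CPM, the count scaled to a common library total, used the TMM-scaled library totals. A fold against a group with 0 reads in all its libraries was computed against a floor of 3 counts over that group's reads, and covers counting error only. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and Python 3.11.15.

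The test was run on simulated counts with 200 transcripts of at least 1 CPM changed by 1.5-, 2- or 4-fold. Of the transcripts changed 2-fold, 44.8% were called for males, 55.2% for females, 16.4% for the difference between sexes, 71.6% for the mean of both sexes and 76.1% for females against males. At 1.5-fold these shares were 10.4%, 23.9%, 1.5%, 31.3% and 32.8%, and at 4-fold 83.3%, 89.4%, 65.2%, 92.4% and 86.4%. The numbers of false calls in the simulations of these contrasts were 2, 5, 7, 10 and 9. Each share comes from a single simulation with 66 or 67 transcripts changed by that fold, and differences between contrasts were not tested. Counts were drawn independently for each transcript and library. The simulation thus lacks deviations of whole libraries such as the real data hold, and the shares may be higher than in the real data.

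A test of whole profiles was chosen after the data had been examined. For each sex the root mean square, over the 61692 transcripts, of the difference in mean log2 CPM (prior count 2) between the 2 arms was compared with its value in all 924 arrangements of the 12 libraries into arms of 6, an exact permutation test. The difference of the male and female effects, their mean, and the Pearson correlation of the effects across transcripts were compared with all 853776 joint arrangements. Transcripts are not independent replicates, and the permutation of animals takes their dependence into account.

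The alternatives planned before the data were examined were DESeq2, limma voom with sample quality weights, robust edgeR, DESeq2 size factors or upper-quartile factors, no filter, a filter of 1 CPM in 12 libraries, an offset for effective length, the second quantification table, each sex alone, 2 surrogate variables, a threshold of 0.1 and leaving out each library. The transcripts named were to be those past the threshold, or the 10 higher and 10 lower ones with the largest change among those with a mean of at least 1 CPM where more than 20 passed, together with the 10 of smallest p where fewer than 5 passed. Since the identifiers carry no names, at most 2 that were higher and 2 that were lower are printed for each comparison. The 60 pairs of libraries within groups were checked for repeated deposits over transcripts with at least 20 reads. The lowest median chi-square of a pair was 1.92, where sampling noise alone gives 0.455, so each library was counted as a sample of its own. The labels give each sample an animal number but no litter. Animals of a group may be littermates, and so may males and females of a treatment, whose numbers lie 2 to 5 apart in 12 pairs. The 853776 joint arrangements count each animal as independent, and p-values measure the spread between these animals. They name no library batch.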

Results

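Gene expression in the midbrain of adult mice was compared between offspring of dieldrin-dosed and of control mothers. There were 6 control males, 6 dieldrin males, 6 control females and 6 dieldrin females. The libraries held 24101453 to 38099023 estimated reads in control males, 30364552 to 50242289 in dieldrin males, 41335057 to 46891822 in control females and 31101608 to 46768473 in dieldrin females. After filtering, 61692 transcripts were tested. They are given by identifier, since the tables used here do not pair them with genes.

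The first comparison asked which transcripts differed in male offspring after developmental exposure. A single transcript passed the threshold. ENSMUST00000152718.1, of 990 bases, had 3 to 19 reads in each control male and 0 reads in all 6 dieldrin males. Its mean was 0.316 CPM ± 0.170 (SD, n = 6) in control males, so that its level in dieldrin males was at least 26-fold lower (floor of 3 counts over the group; edgeR adjusted p = 0.0407). In females it was at 0.372 CPM ± 0.289 (SD, n = 6) in controls and 0.250 CPM ± 0.0846 (SD, n = 6) with dieldrin. The transcripts with the smallest p among those that were higher with dieldrin did not pass. ENSMUST00000132588.7 was at 1.11 CPM ± 0.134 (SD, n = 6) in controls and 2.85 CPM ± 0.842 (SD, n = 6) in dieldrin males, a log2 fold change of 1.36 (SE 0.231; edgeR adjusted p = 0.18), and ENSMUST00000135092.1 was at 0.331 CPM ± 0.181 (SD, n = 6) and 0.996 CPM ± 0.167 (SD, n = 6), a log2 fold change of 1.58 (SE 0.293; edgeR adjusted p = 0.363). Without adjustment, 5605 transcripts had p under 0.05, 3544 of them higher and 2061 lower with dieldrin, and 4 of 27 splits of the males, the real one included, had as many, up to 7896. With limma voom the directions were 2695 higher and 2852 lower. With 2 surrogate variables 1321 were higher and 2562 lower, and without dieldrin male replicates 2 and 5 1201 were higher and 1647 lower. The other settings kept more transcripts higher than lower. The count was 9615 without dieldrin male replicate 1 and 2581 with males fitted alone. DESeq2 called 153 transcripts, 84 higher and 69 lower, and limma voom 0. The call for ENSMUST00000152718.1 was lost when any of 16 of the 24 libraries was left out, and 47 transcripts passed without dieldrin male replicate 1.

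In females no transcript passed the threshold with edgeR, and the smallest adjusted p was 0.344. Without adjustment 5092 transcripts had p under 0.05, of which 1962 were higher and 3130 lower with dieldrin, and the count was 3193 without dieldrin female replicate 5, 7785 with females fitted alone, 8453 with limma voom, 8380 without dieldrin male replicates 2 and 5 and 9706 with 2 surrogate variables. The last of these held 4918 higher and 4788 lower. With an offset for the trend on transcript length 2684 were higher and 2528 lower. DESeq2 called 210 transcripts, 134 higher and 76 lower, and limma voom 5, 4 higher and 1 lower. The values with the smallest p among transcripts that were higher were those of ENSMUST00000175887.7, at 2.14 CPM ± 0.543 (SD, n = 6) in controls and 5.06 CPM ± 1.71 (SD, n = 6) with dieldrin, and of ENSMUST00000088357.11, at 89.0 CPM ± 5.74 (SD, n = 6) and 120 CPM ± 17.6 (SD, n = 6). Among transcripts that were lower, ENSMUST00000125924.1 was at 8.92 CPM ± 1.28 (SD, n = 6) in controls and 5.37 CPM ± 0.703 (SD, n = 6) with dieldrin, and ENSMUST00000231696.1 was at 3.49 CPM ± 0.336 (SD, n = 6) and 2.17 CPM ± 0.358 (SD, n = 6). The log2 fold changes of these 4 were 1.24 (SE 0.242), 0.43 (SE 0.084), -0.73 (SE 0.13) and -0.69 (SE 0.136).

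Over whole profiles, the arms of the females lay further apart than most arrangements of the same animals. The root mean square log2 difference between dieldrin and control females was 0.543, against a median of 0.469 over the 924 arrangements, and 4 arrangements, the real one and its mirror included, were as large (exact permutation p = 0.00433). In males the difference was 0.586 against a median of 0.551 (exact permutation p = 0.0996). Without dieldrin male replicate 1 the male value was 0.657 (exact permutation p = 0.00216, the smallest that the arrangements of the 11 libraries can give). Without dieldrin male replicates 2 and 5, which correlated least with the other libraries, it was 0.559 against a median of 0.555 (exact permutation p = 0.371). In females 810 transcripts, or 1.31%, had every dieldrin library on the same side of every control library, 371 of them higher and 439 lower, where chance gives 0.216%. Of the 462 splits of the females, 2 had as many, and the highest other split had 1288. In males 135 transcripts, or 0.219%, were fully separated in this way.

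**Figure D1:**
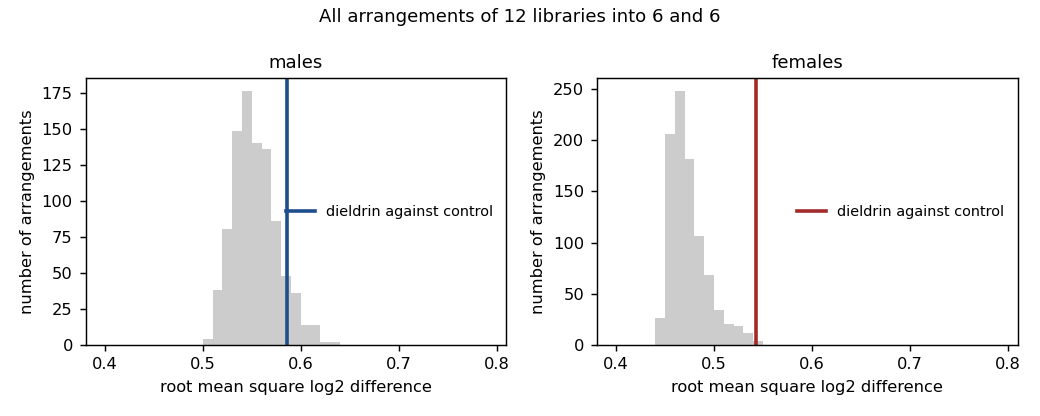
Number of arrangements of the 12 male (left) and 12 female (right) libraries into arms of 6, by the root mean square log2 difference between the arms over 61692 transcripts, with the real arms as a vertical line. The real value was 0.586 in males and 0.543 in females, both inside the range of the other arrangements. In females 4 of 924 arrangements reached it, the real one and its mirror included.

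The effect of dieldrin was then compared between the sexes. For 3 transcripts the effects differed, and each had opposite signs in males and females. ENSMUST00000190723.6, of 6141 bases, was at 223 CPM ± 8.98 (SD, n = 6) in control males and 148 CPM ± 33.4 (SD, n = 6) in dieldrin males, and at 173 CPM ± 19.9 (SD, n = 6) in control females and 254 CPM ± 35.8 (SD, n = 6) in dieldrin females. Its log2 fold change was 1.14 greater in females than in males (SE 0.17; 95% confidence interval 0.791 to 1.496). ENSMUST00000059331.8, of 2173 bases, was at 16.3 CPM ± 0.969 (SD, n = 6) and 12.2 CPM ± 0.868 (SD, n = 6) in control and dieldrin males, and at 15.5 CPM ± 1.05 (SD, n = 6) and 19.2 CPM ± 2.47 (SD, n = 6) in the corresponding females. The difference of its log2 fold changes was 0.72 (SE 0.112; 95% confidence interval 0.49 to 0.95). ENSMUST00000125924.1, of 5823 bases, went the other way, from 6.93 CPM ± 1.35 (SD, n = 6) to 9.61 CPM ± 1.23 (SD, n = 6) in males and from 8.92 CPM to 5.37 CPM in females, a difference of -1.20 (SE 0.183; 95% confidence interval -1.58 to -0.82). The edgeR adjusted p was 0.0336 for each of the 3. None of the 3 passed with DESeq2 size factors or without a filter. They also did not pass without the 3 libraries in which a single transcript took over 3% of the reads. The number of calls lay between 0 and 309 when single libraries were left out, and was 0 for most of these.

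**Figure D2:**
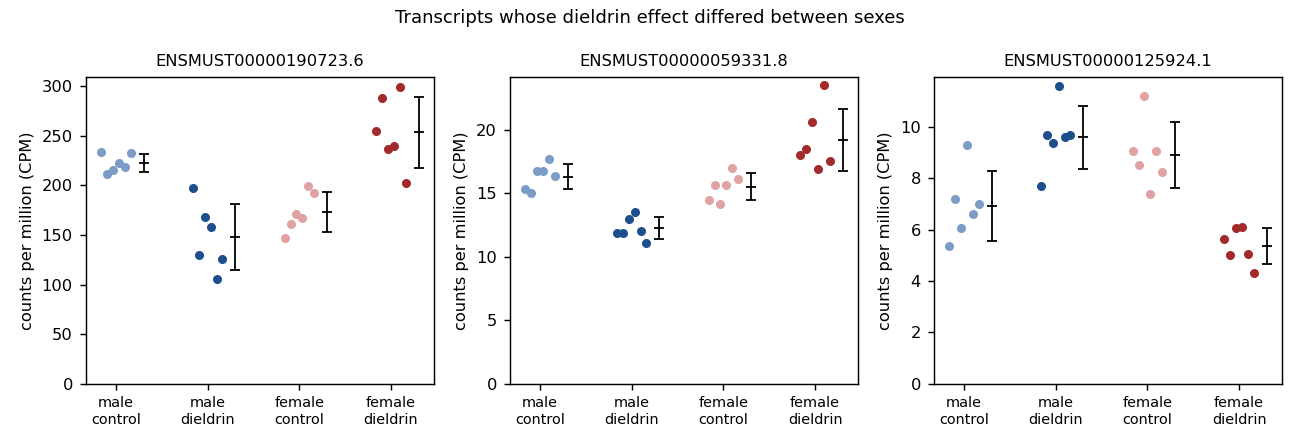
CPM of the 3 transcripts whose dieldrin effect differed between the sexes. Each point is an animal (n = 6 per group) and the bar beside it gives the mean and SD. The first pair of transcripts was lower with dieldrin in males and higher in females, and ENSMUST00000125924.1 was the reverse.

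Other tests called many more transcripts in this comparison, 1041 with DESeq2 and 745 with limma voom. These tools use the same 24 libraries, and 511 transcripts were called by both. DESeq2 was not run on other splits of the animals, so how many transcripts it calls by chance was not measured, here or in the other comparisons. Among all tested transcripts, 664 had an unadjusted edgeR p under 0.05 in both sexes. Of these, 611 changed in opposite directions and 53 in the same direction, where independent lists would give 245.1 and 216.9. Most of the excess lay in those lower with dieldrin in males and higher in females, 370 against 65.4 for independent lists. Those higher in males and lower in females numbered 241 against 179.7. Control males and dieldrin females also hold the 3 libraries in which a single transcript took over 3% of the reads. The counts by direction were not repeated without these libraries or in other splits of the animals. Transcripts vary together across libraries, so how far such counts depart from independent lists by chance was not measured. The correlation of the male and female log2 differences across transcripts was -0.133 (exact permutation p = 0.00171 over joint arrangements of 6 and 6 animals in each sex), and the whole-profile difference of the 2 effects had an exact permutation p of 0.000213.

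**Figure D3:**
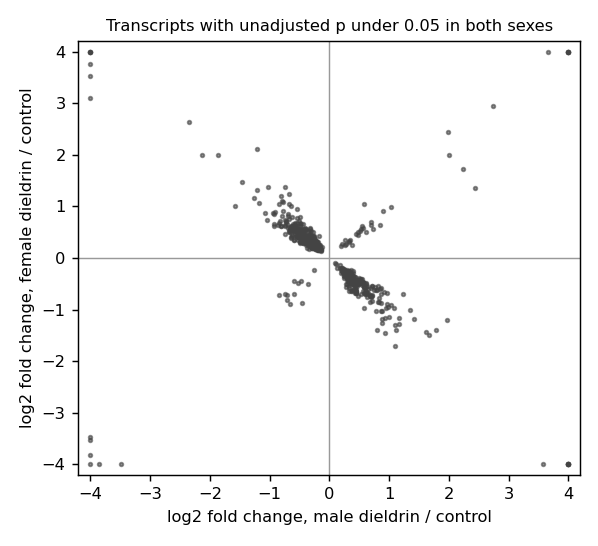
Log2 fold change of dieldrin against control in males (horizontal) and females (vertical) for the 664 transcripts with an unadjusted p under 0.05 in each sex, a point per transcript. The 26 transcripts with a change beyond 4 either way are drawn at 4 or -4, and 611 of the 664 lie in the quadrants of opposite sign.

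For the mean of the male and female effects no transcript passed with edgeR, the smallest adjusted p was 0.135, and 2724 transcripts had an unadjusted p under 0.05 (4356 without dieldrin male replicate 1). DESeq2 called 68 and limma voom 0. The smallest p belonged to ENSMUST00000152718.1, the transcript described for males. ENSMUST00000206394.1, with a log2 fold change of 0.81 (SE 0.191; edgeR adjusted p = 1), was at 1.07 CPM ± 0.357 (SD, n = 6) and 1.60 CPM ± 0.591 (SD, n = 6) in control and dieldrin males and at 0.723 CPM ± 0.243 (SD, n = 6) and 1.505 CPM ± 0.337 (SD, n = 6) in the corresponding females. ENSMUST00000105939.9 had 0 reads in all 6 control males and 2.36 CPM ± 2.12 (SD, n = 6) in dieldrin males, and 0.0405 CPM ± 0.0992 (SD, n = 6) and 1.40 CPM ± 2.18 (SD, n = 6) in control and dieldrin females, so that it was spread unevenly within the dieldrin groups. ENSMUST00000135432.7 was at 0.792 CPM ± 0.536 (SD, n = 6) in control males and had 0 reads in all 6 dieldrin males, and was at 0.333 CPM ± 0.336 (SD, n = 6) and 0.0319 CPM ± 0.0782 (SD, n = 6) in the corresponding females (edgeR adjusted p = 1 for each). The whole-profile test of the mean effect gave an exact permutation p of 0.248.

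Females and males, averaged over treatments, differed in 243 transcripts, 76 higher and 167 lower in females. A set of 7 transcripts had at least 50 reads in all 12 males and at most 3 in all 12 females, and 0 transcripts showed the reverse. None of 100 random splits of the 24 libraries gave such a transcript. ENSMUST00000188484.1 and ENSMUST00000154004.7 had 0 reads in all 12 females. Their means over the 12 males were 25.5 CPM ± 4.82 (SD) and 17.1 CPM ± 4.17 (SD), at least 4110-fold and 2760-fold above a floor of 3 counts over the females (edgeR adjusted p = 1.37e-11 and 2.24e-10). Summed over the 7 transcripts, control males had 75.2 CPM ± 3.56 (SD, n = 6) and dieldrin males 77.2 CPM ± 15.1 (SD, n = 6). The transcripts with the largest increase in females, at a mean of 1 CPM or more, varied widely within groups. ENSMUST00000191695.1 was at 1.59 CPM ± 1.32 (SD, n = 6) and 0.676 CPM ± 0.505 (SD, n = 6) in control and dieldrin males and at 6.15 CPM ± 6.19 (SD, n = 6) and 9.23 CPM ± 5.32 (SD, n = 6) in the corresponding females, a log2 fold change of 2.86 (SE 0.602; edgeR adjusted p = 0.04). ENSMUST00000114574.1 had a log2 fold change of 2.12 (SE 0.441; edgeR adjusted p = 0.0387). The call for ENSMUST00000191695.1 was lost when any of 15 of the 24 libraries was left out, and that for ENSMUST00000114574.1 with any of 14. Without adjustment 12577 transcripts had p under 0.05, 4989 higher and 7588 lower in females. With DESeq2 6585 were higher and 7421 lower without adjustment. DESeq2 called 4696, 2145 higher and 2551 lower, and limma voom 4561, 2136 higher and 2425 lower. Leaving out single libraries gave 65 to 4461 calls with edgeR, the highest without dieldrin male replicate 1.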

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

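The whole-profile tests, their repeats after thinning, after removing the length trend and without libraries, and the comparison of unadjusted counts between splits were chosen after the results they follow up had been seen, and the exchange of labels was considered only afterwards.

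Several libraries stood apart from the other 5 of their group. A single transcript took 8.45% of the reads of control male replicate 5, where the most abundant transcript took 2.09% to 2.39% in the other control males, and 11.8% in dieldrin female replicate 1, against 2.22% to 3.55% in the others. The TMM factor of dieldrin male replicate 5 was 1.16, against 0.971 to 1.03. ENSMUST00000132588.7 was at 2.39 CPM in dieldrin female replicate 2 (others 0.883 to 1.44), ENSMUST00000175887.7 at 3.18 CPM in control female replicate 5 (others 1.67 to 2.12) and ENSMUST00000231696.1 at 4.82 CPM in control male replicate 2 (others 3.10 to 3.48). ENSMUST00000105939.9 was at 0.243 CPM in control female replicate 3 and ENSMUST00000135432.7 at 0.191 CPM in dieldrin female replicate 1, each with 0 reads in the other 5 libraries. Control male replicate 6 had the highest values of both transcripts named as higher in females, 4.08 CPM of ENSMUST00000191695.1 (others 0.499 to 1.82) and 1.94 CPM of ENSMUST00000114574.1 (others 0.630 to 0.855). In all, 10 of 79 sets of 6 values held such a value, where chance gives about 1 in 20.

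Dieldrin females lay apart from control females over the whole profile (exact permutation p = 0.00433). Depth did not account for it: with every library thinned to the total of the shallowest, the largest p of 10 thinnings was 0.00433. Removing each library's trend on transcript length left p at 0.00433, and without the 3 libraries in which a single transcript took over 3% of the reads it was 0.00952. Without these libraries 3204 of 64372 transcripts had an unadjusted p under 0.05 in females, in a fit with fewer animals. That is no more than the share that uniform p-values would give. With all libraries the number was 5092 of 61692. Uniform p-values would give 3085 of 61692, and the other splits of all females had a median of 892.5. The count of calls decides nothing about chance, since with 0 real calls all 27 of 27 splits have as many by construction (highest other 1). For the 5092 transcripts with an unadjusted p under 0.05, 1 of 27 splits had as many, the real one. The highest other had 2396, but so few splits cannot exclude chance. Without dieldrin female replicate 5 the number was 3193 of 62708, also near the share that uniform p-values would give. Over all 924 arrangements of the females, another grouping and its mirror gave a larger root mean square difference, 0.548 against 0.543. A difference in dissection, in litter or in the order of preparation, none of which the labels give, was not tested and stays open beside the exposure.

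The effects of dieldrin in males and females differed for 3 transcripts. Over the whole profile, the root mean square of the female effect minus the male effect was 0.8495. Its median over the joint arrangements was 0.7261 (exact permutation p = 0.0002132). That value also grows where the arms of either sex lie far apart, and it does not compare the sizes of the effects. For ENSMUST00000190723.6, ENSMUST00000059331.8 and ENSMUST00000125924.1 the differences were 1.143, 0.722 and -1.203 on the log2 scale, with opposite signs in males and females. Across all tested transcripts the effects correlated at -0.133 (exact permutation p = 0.00171), only a weak tendency to opposite directions. Of 27 splits of the animals within each sex, 1 gave as many calls, the real one (3 calls, highest other 0), but so few splits cannot exclude chance. With limma voom 1 of 23 splits was as large, 745 calls against at most 1. The edgeR count was 0 with DESeq2 size factors, without a filter and with pairs of nearest animal numbers as a block. It was also 0 in most fits that left out a single library. Some settings gave more, up to 868 with 2 surrogate variables. The correlation of effects kept its p below 0.05 after thinning (largest p 0.00205), after removing the length trend (0.00176), without the 3 libraries with an abundant transcript (0.00857) and without dieldrin male replicates 2 and 5, which correlated least with the other libraries (0.000825). What stays open is an effect of exposure that depends on sex, a hypothesis found and tested on the same data, and an exchange of the control and dieldrin labels within a sex. After such an exchange the 3 calls would by construction become calls for the mean of both sexes, so the 2 cannot be told apart with these tables. In both sexes the labels give control animals lower animal numbers than dieldrin animals. A preparation order that ran differently in males and females was not tested.

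For the single call in males, 3 of 27 splits gave as many (highest other 1), and for the 5605 transcripts with an unadjusted p under 0.05, 4 of 27 (highest other 7896), so chance cannot be excluded for either. For the mean of both sexes the 0 calls are met by 27 of 27 splits by construction (highest other 0), which decides nothing, and the 2724 transcripts with an unadjusted p under 0.05 by 5 of 27 (highest other 3618), so chance cannot be excluded for that number. For females against males 1 of 27 splits within treatments gave as many calls, the real one (243, highest other 0). No other split drawn came near that number, a limited test with so few splits. The labels give no batch. The deposited tables are numbered in separate ranges for males and females, with the controls of each sex first, and whether this follows the order of preparation is not given in the sources used here. A preparation of males and females at different times may contribute to the sex difference and was not tested.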

How the results depend on the processing

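Where a count moved by over 1.5 times, the cause was not tested unless named. DESeq2 in place of edgeR gave 153 calls in males, 210 in females, 1041 for the difference between sexes, 68 for the mean of both sexes and 4696 between the sexes. Limma voom with quality weights gave 0, 5, 745, 0 and 4561. A filter of 1 CPM in 12 libraries, which removes the transcript called in males, gave 0 there, 15 for the difference and 932 between the sexes, and no filter gave 0 for the difference and 74 between the sexes. DESeq2 size factors gave 0 for the difference. A threshold of 0.1 gave 46 and 3305 for the difference and between the sexes. With 2 surrogate variables there were 0 calls in males, 868 for the difference and 79 between the sexes. Each sex fitted alone gave 0 in males, where the filter on males alone removes the transcript called in the main fit, and 0 in females. Of the settings added after seeing the data, leaving out the 3 libraries with an abundant transcript gave 1 for the difference and 44 between the sexes. That 1 was not among the 3 transcripts called in the main fit. The count in males stayed at 1, but that call was higher with dieldrin, and ENSMUST00000152718.1 did not pass. Leaving out dieldrin male replicates 2 and 5 gave 0 in males and 8 for the difference. A minimum mean of 5 CPM, which also removes the male call, gave 0 in males, 31 for the difference and 896 between the sexes. Robust edgeR, upper-quartile factors, the effective length offset and an offset for the length trend kept every count within 1.5 times. The second quantification table, identical to the first, tested nothing.

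Leaving out each of the 24 libraries in turn gave 0 to 47 calls in males, 0 to 2 in females, 0 to 309 for the difference, 0 to 1 for the mean of both sexes and 65 to 4461 between the sexes, the highest in males, for the difference and between the sexes without dieldrin male replicate 1. Whole-profile p ranged from 0.00216 to 0.247 in males (past the threshold without dieldrin male replicate 1), 0.00216 to 0.0238 in females, 4.68e-06 to 0.0016 for the difference, 0.0642 to 0.463 for the mean and 0.000122 to 0.0141 for the correlation. Over all settings, 122 of 738 log2 fold changes of named transcripts lost and 17 gained significance. All kept their sign, a weak test as the fits share most libraries. Not run, for want of a pairing of transcripts with genes, were tests per gene, the fixed gene lists (camera, fry, and with surrogate variables) and the genes fixed by name, and, for want of named litters, fits with litter as a block. The replicate numbers only name samples, so males and females were paired by nearest animal number, a choice made after seeing the data. The deviations of the 12 pairs from their group means correlated at -0.0859 to 0.0412 across transcripts, none over 0.1, and in 2 pairs both libraries correlated best with each other. With the pairs as a block there were 0 calls for the difference and 26 between the sexes. In simulated data this block recovered 4.5% and 56.7% of the transcripts changed 2-fold in these comparisons. In the 924 arrangements that keep the pairs together the whole-profile p was 0.00433 for the difference, 0.156 for the mean and 0.00866 for the correlation. Depth limits transcripts with few reads: the male call rests on 3 to 19 reads per control library.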

Other observations

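ENSMUST00000217116.1, of 3756 bases, led the reads of 3 libraries, with 8.45% in control male replicate 5, 11.8% in dieldrin female replicate 1 and 3.55% in dieldrin female replicate 2. In the other 21 libraries its share was 0% to 1.28%, with a median of 0.0263%. The 3 libraries belong to 2 groups, control males and dieldrin females, and the tables used here do not pair this transcript with a gene.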
